A study of Mus musculus with 6 samples.

How the data were processed

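RNA sequencing was used to measure gene expression in 6 mouse prostate samples of a single genotype, a mouse model of prostate cancer that was the same in both groups. Per the labels' protocols, total RNA was isolated with a column kit and DNase treatment, and libraries followed a standard Illumina protocol. The labels put 2 samples in the intact group and 4 in the castrated group. They do not give the time since castration, and they do not say that the samples come from separate animals, so p-values measure only the spread between these samples, which may be technical.

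The authors deposited 1 table of CPM (reads per 1000000 reads counted in genes) per sample, with 24421 gene symbols in the same order in each. The submitters' processing notes name TopHat2, HTSeq and edgeR without versions, and the genome build mm10. How these tools were set, and whether counting used the strand, is not given in the sources used here. Each deposited CPM column summed to 1000000, with no further scaling between samples. In each sample 100% of the values were whole multiples of the smallest value above 0, within a tolerance of 1e-06, so whole reads could be recovered: 43679297 and 58440892 in the intact samples and 53191083, 56162041, 55864253 and 59170793 in castrated samples 1 to 4. A count of 0 in a sample allows up to 3 reads, or 0.0507 to 0.0687 CPM depending on the sample. Such floors, and intervals on read ratios, cover counting error only.

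CPM values were divided by median-of-ratios size factors, which ranged from 0.978 to 1.05, and are called rescaled CPM. Genes with a deposited CPM of at least 1 in at least 2 samples were tested, 13898 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(rescaled CPM + 0.5), with empirical Bayes moderation and a mean-variance trend, for castrated minus intact samples. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(value + 0.5) scale, which understates the change of weakly expressed genes. Where a gene had 1 to 3 reads in a group, the ratio of reads is given with its exact 95% binomial interval.

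The test, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The 34 lists cover androgen receptor targets, translation, metabolism and the cell types a prostate sample could hold. The 31 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated and with fry. The rule names 5 genes of cap-dependent translation whatever their values, and some genes it selects are not reported here. It then takes the 10 largest rises and the 10 largest falls among called genes with non-overlapping groups and a mean of at least 5 rescaled CPM, leaving out numbered gene models. From each list with a camera call, or with at least 3 called members, it takes the 3 called members with the smallest p. Members of a list for an unexpected tissue are given as values where that list moves.

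The alternatives were other pseudocounts, filters, scalings and moderation settings, sample weights, each sample left out in turn, the replicate number as a block, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. The steps were tested on simulated counts with 200 changed genes, drawn 5 times for the comparison of castrated with intact samples, over about 13751 genes. limma recovered 34.6% of genes changed 2-fold, 88.7% of those changed 4-fold and 96.1% of those changed 8-fold, with 7.24% of its calls false. edgeR recovered 33.7%, 88.1% and 97.0%, with 5.08% false, and DESeq2 66.3%, 94.6% and 97.3%, with 27.3% false. In 5 simulations of lists, camera called the changed list 5 times and 0 of 150 unchanged lists, with genes that varied independently.

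Gene positions are from the GENCODE annotation of GRCm38, the assembly that mm10 names. Exons of named genes were compared with those of other genes, since reads in shared stretches cannot be assigned.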

Results

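Gene expression was compared in prostates of a mouse model of prostate cancer between 2 intact and 4 castrated samples. Castration removes the main source of androgens, the ligands of the androgen receptor, and the study's title places the work on that receptor and translation in advanced prostate cancer. Between 43679297 and 59170793 reads per sample were counted in genes. On log2 values, the first principal component held 48.7% of the variance and the second 27.4%. Castrated sample 4 lay apart from castrated samples 1 and 3 on both. Correlations between castrated samples ranged from 0.941 to 0.988, the intact pair correlated at 0.979, and correlations between the groups ranged from 0.941 to 0.952. No pair of samples agreed within sampling noise (chi-square per degree of freedom of 57.8 or more).

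**Figure D1:**
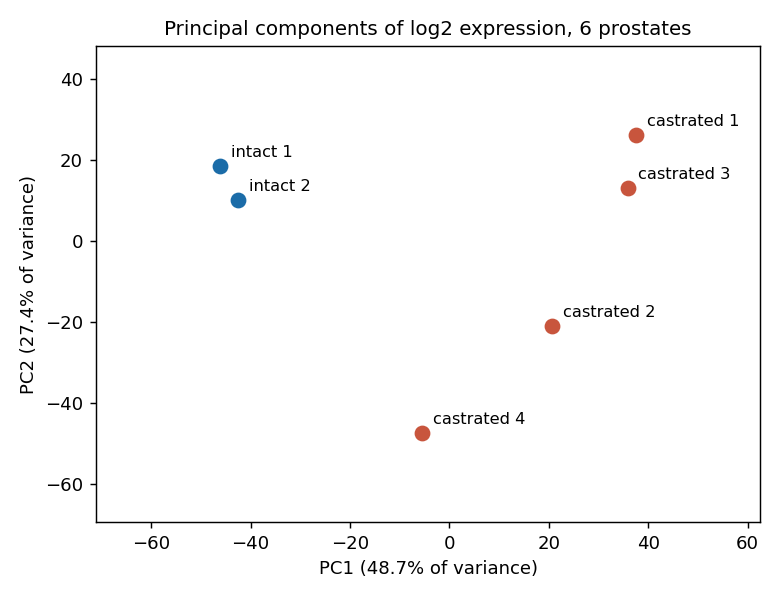
Principal components 1 and 2 of log2 expression, 1 point per sample, intact in blue and castrated in red, with the share of variance on each axis. The intact samples lie at -46.1 and -42.5 on the first component, castrated samples 1 to 3 at 20.6 to 37.5 and castrated sample 4 at -5.46.

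Of 25 tested androgen receptor targets, 8 were lower and 0 higher in castrated prostates (camera adjusted p = 0.000556, and adjusted p = 0.17 with an estimated correlation). Fkbp5, a co-chaperone of steroid receptors (chromosome 17, 28399094 to 28517527), fell 7.70-fold, from 254 ± 1.97 rescaled CPM (SD, n = 2) in intact to 32.5 ± 2.09 (n = 4) in castrated samples. Zbtb16, a transcriptional repressor (chromosome 9, 48654297 to 48836222), fell 13.1-fold, and Bmpr1b, which encodes a bone morphogenetic protein receptor (chromosome 3, 141837136 to 142169425), fell 24.1-fold. Foxi1, a transcription factor of acid-secreting epithelial cells (chromosome 11, 34204338 to 34208089), rose from 0.548 ± 0.709 to 25.5 ± 14.1 rescaled CPM. The neutrophil calprotectin genes S100a8 and S100a9 rose 5.86-fold and 5.48-fold, which became 3.47-fold and 3.70-fold without intact sample 2, and 9.87-fold and 8.09-fold without intact sample 1.

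In limma with Benjamini-Hochberg adjustment, 97 genes were higher and 177 lower in castrated samples, 274 of 13898 tested. The groups did not overlap in any of these 274 genes, against 26.6% of all tested genes and 13.3% by chance. The calls select genes whose groups lie apart, so the lack of overlap in the 274 is no separate support for them. The count depended on single libraries: it was 9 and 1 without intact sample 1 or 2, from 46 to 83 without castrated sample 1, 2 or 3, and 1052 without castrated sample 4. On the recovered reads edgeR called 203 genes, 54 higher and 149 lower, of which limma also called 200, and DESeq2 called 1293, 662 higher and 631 lower. Higher genes thus made up 35.4% of the calls in limma, 26.6% in edgeR and 51.2% in DESeq2. With 1 castrated sample left out, they made up from 17.4% (without castrated sample 3) to 44.3% (without castrated sample 4). Without intact sample 1 or 2, genes expressed in intact samples alone fell below the filter, so those fits could not call them.

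**Figure D2:**
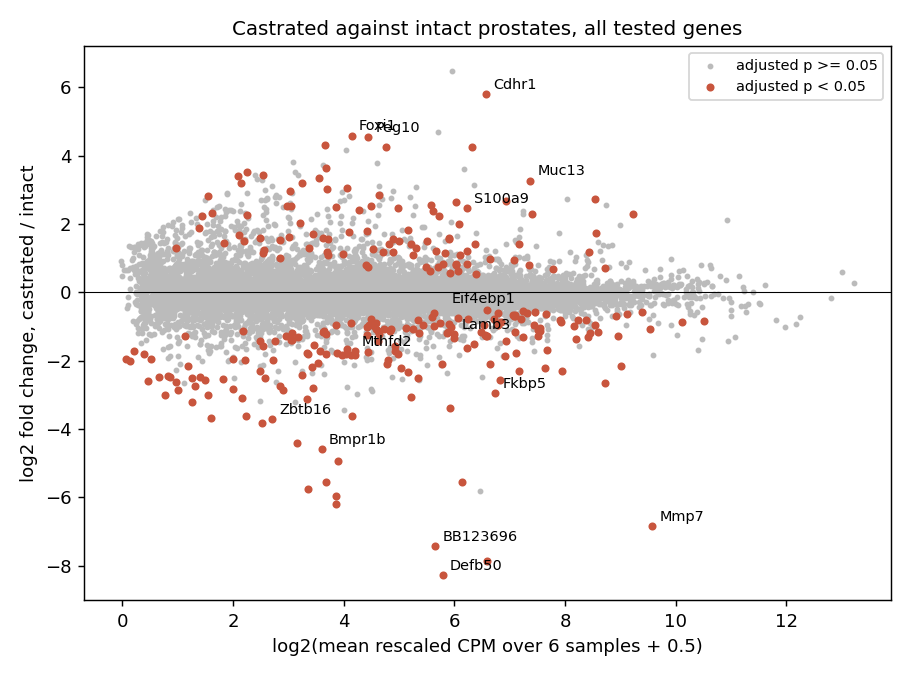
Log2 fold change, castrated over intact, against log2 mean rescaled CPM for each of the 13898 tested genes, with genes at an adjusted p under 0.05 in red. Called genes number 97 above and 177 below 0, and Defb50 and Mmp7 are among the largest falls.

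Of the genes named here for the question of cap-dependent translation, 0 passed the threshold in limma, edgeR or DESeq2, or had an unadjusted p under 0.05 in limma, and the 95% interval of each log2 difference included 0. Eif4ebp1, an inhibitor of the cap-binding protein (chromosome 8, 27260329 to 27276674), was at 67.7 ± 14.2 and 49.9 ± 15.3, a log2 difference of -0.48 with an interval of -1.24 to 0.28 (limma adjusted p = 0.546). Its relative Eif4ebp2 had a log2 difference of -0.41 with an interval of -1.05 to 0.22. Intervals were narrower for Eif4e, which binds the cap (-0.22 to 0.32), the scaffold Eif4g1 (-0.22 to 0.28) and the helicase Eif4a1 (-0.34 to 0.35). Other genes on the same strand cover 6.62% of the exon bases of Eif4a1. Of 13 cap-binding genes and 32 other initiation factors tested, 0 passed the threshold in limma, adjusted over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 3 and 3, edgeR called 0 and 0, and DESeq2 1 and 1. The median log2 fold changes of these lists were both 0.01. The 3 cap-binding genes at an unadjusted p under 0.05 in limma moved both ways: Eif4a2 by 0.36, Pdcd4 by 0.52 and Mknk2 by -0.35. The mixed form of fry, which tests for members that move in either direction, gave the cap-binding list an adjusted p of 0.0304. It gave the other initiation factors 0.263. RNA levels alone were measured, not protein or translation.

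Adjusted over the list alone, 9 of the androgen receptor targets fell and 1 rose. Besides Fkbp5 and Zbtb16, Bmpr1b fell from 33.2 ± 8.40 to 0.902 ± 0.314. The other 17 did not pass over all genes, and the list's median was -0.24. Of 11 prostate secretory genes, 4 fell and 0 rose, and 7 fell adjusted over the list alone (camera adjusted p = 1.21e-07, and adjusted p = 0.333 with an estimated correlation). The defensin gene Defb50 (chromosome 8, 21823539 to 21831296) had 17205 reads in the intact and 2 in the castrated samples, a ratio of 18900 with an interval of 5232 to 156100. 9530002B09Rik fell from 284 ± 6.79 to 1.27 ± 1.77, 233-fold and 355-fold without castrated sample 1, and Spink1, a protease inhibitor, had 368 and 2 reads, a ratio of 404 with an interval of 111 to 3351. Msmb, named after its values were seen as the fourth, had 837 reads in intact and 0 in castrated samples, at least 572-fold lower against a floor of 3 reads over the group. It was at 2.65 and 12.7 rescaled CPM in intact samples 1 and 2, so this bound rests largely on intact sample 2. Defb50, Spink1 and Msmb already lay below the list's median of -2.58, so placing them at their bounds could not move it. Seminal vesicle genes stayed below the filter in both groups.

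Other large falls included Mmp7, a matrix metalloprotease (chromosome 9, 7692090 to 7699585), from 2245 ± 1469 to 17.5 ± 5.45. An antisense gene covers 11.5% of the exon bases of Mmp7. The complement gene C7 fell 46.9-fold, the blood group transferase gene Abo 53.9-fold, Mroh4 73.1-fold and the noncoding BB123696 172-fold. The pseudocount limits these folds: edgeR, fitted to the reads, gave log2 changes of -6.87 for C7, -9.15 for Abo (2868 reads in intact and 11 in castrated samples), -8.93 for Mroh4 (4099 and 19 reads) and -8.63 for BB123696. Spink5, a protease inhibitor, fell 47.1-fold and Reg3b, an antimicrobial lectin, 30.7-fold, and both varied more between samples. With 1 sample left out, Spink5 kept its call in 2 of 6 fits and Reg3b in 1. The fall was 17.6-fold for Reg3b and 69.8-fold for Mmp7 without intact sample 2, 54.0-fold and 190.0-fold without intact sample 1, and 75.8-fold for Spink5 without castrated sample 2. edgeR gave Spink5 an adjusted p of 0.0741 and DESeq2 gave it none. The calls of Mmp7 without intact sample 2 (adjusted p = 0.0561) and of Bmpr1b without intact sample 1 or 2 (adjusted p = 0.0802 and 0.0813) were lost. That of 9530002B09Rik was lost without intact sample 1 or 2 or castrated sample 3 (adjusted p = 0.137, 0.126 and 0.0524) and in edgeR (adjusted p = 0.0521). The calls of 5 of the 10 largest falls (Defb50, BB123696, Mroh4, Abo and C7) held in each of the 17 fits in which they were tested. Without intact sample 1 or 2 these 5 fell below the filter and were not tested.

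The largest rises by the rule included 2 subunits of the vacuolar proton pump beside Foxi1. Atp6v0d2 (chromosome 4, 19876841 to 19922605) rose from 1.68 ± 1.58 to 39.0 ± 17.9 and Atp6v1g3 (chromosome 1, 138273738 to 138289462) from 0.332 ± 0.371 to 18.2 ± 10.03. Cdhr1, a protocadherin, rose 55.4-fold, the imprinted gene Peg10 23.3-fold, and Crym, a thyroid hormone binding protein, 19.2-fold. The trypsinogen gene Prss2, which has close paralogs that may share reads, rose 12.4-fold, Bmp3 10.7-fold, Wdr72 10.1-fold and the mucin gene Muc13, of whose exon bases an antisense gene covers 6.06%, 9.61-fold. Without castrated sample 4 all 10 were called, and with any other single sample left out only Bmp3 was, in 1 of 5 fits. The size of 7 of the 10 rises moved by over 1.5 times with 1 sample left out. Without intact sample 1 or 2, the rise was 14.2-fold or 40.3-fold for Foxi1, 10.7-fold or 33.3-fold for Atp6v0d2, 13.7-fold or 39.6-fold for Peg10, 9.72-fold or 37.8-fold for Crym, 5.90-fold or 17.4-fold for Wdr72 and 19.3-fold or 8.04-fold for Prss2. Cdhr1 rose 89.7-fold without castrated sample 4. In castrated sample 4, 8 of the 10 were lower than in each other castrated sample, among them Foxi1 (7.06 against 23.5 or more), Cdhr1 (24.8 against 129 or more) and Muc13 (93.9 against 169 or more). Bmp3 lay within the range of the others (7.56 against 3.54 to 11.6), and Prss2 above it (30.4 against 10.2 to 15.9). edgeR called 1 of the 10, Cdhr1 (adjusted p = 0.0469), and gave the other 9 adjusted p from 0.05 to 0.0880, the highest for Foxi1. In limma with no filter, Atp6v0d2, Atp6v1g3, Bmp3, Cdhr1, Crym, Foxi1, Muc13 and Wdr72 lost the call (adjusted p from 0.0560 to 0.0844). Without a mean-variance trend, Atp6v1g3, Crym, Foxi1 and Muc13 lost it (adjusted p from 0.0535 to 0.0677).

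**Figure D3:**
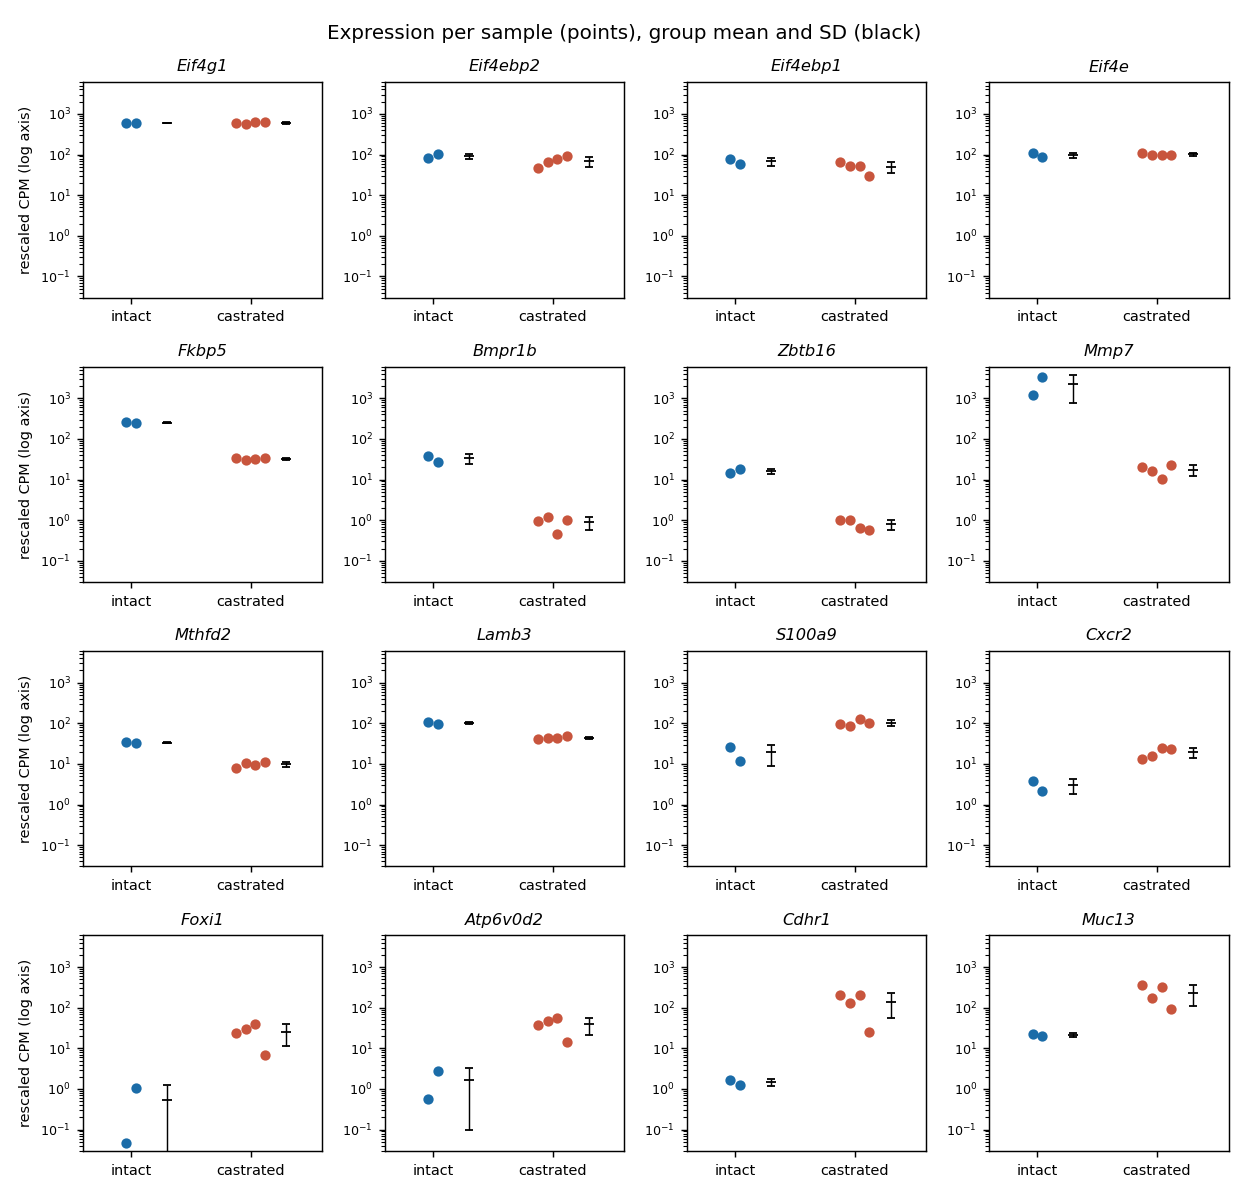
Rescaled CPM on a log axis for 16 genes, with 1 point per sample (intact blue, castrated red) and the group mean and SD in black, the lower SD bar of Foxi1 running off the axis. Fkbp5, Bmpr1b, Zbtb16 and Mmp7 separate the groups, and Eif4ebp1, Eif4g1 and Eif4e overlap.

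Of the 31 lists tested, camera called 17, 5 higher and 12 lower in castrated samples. With an estimated correlation 0 held in camera, at a smallest adjusted p of 0.17 and with 4 at an unadjusted p under 0.05. Estimated correlations of the androgen receptor target, steroid receptor and amino acid response lists were 0.00313, 0.00118 and 0.00196, below the preset 0.01. A higher correlation thus did not end the calls of those lists. In its directional form, which tests whether a list moves on balance one way, fry called 5. These were the androgen receptor targets, the secretory genes, the steroid receptors, the amino acid response and the neutrophil genes.

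Neutrophil genes rose together: 4 of 8 tested rose and 8 rose adjusted over the list alone, with a median of 1.95 (camera adjusted p = 1.65e-08, and adjusted p = 0.274 with an estimated correlation). S100a9 (chromosome 3, 90692632 to 90695721) went from 19.3 ± 10.4 to 101.4 ± 17.2 and the chemokine receptor gene Cxcr2 (chromosome 1, 74153989 to 74161246) from 3.02 ± 1.23 to 19.5 ± 5.72. Csf3r, named after its values were seen, rose with a log2 change of 2.39. Of the 8 tested genes, edgeR called 2 and DESeq2 7. S100a8 lost its call in edgeR (adjusted p = 0.0782), and in limma with no filter (adjusted p = 0.0768) or without a mean-variance trend (adjusted p = 0.0610). With 1 sample left out, S100a9 and Cxcr2 each kept the call in 2 of 6 fits and S100a8 in 1. Macrophage genes had a median of 0.00, T and NK cell genes -0.17 and B and plasma cell genes -0.13, with no call in camera at unadjusted p of 0.529, 0.167 and 0.483. Without intact sample 2, camera called T and NK cell genes (median -0.47, adjusted p = 0.00118) and B and plasma cell genes (median -0.996, adjusted p = 0.00518) lower.

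Basal epithelial genes were called lower, with a median of -0.77 (camera adjusted p = 0.000109, and adjusted p = 0.667 with an estimated correlation). Of 14, 2 fell, and 4 fell adjusted over the list alone. The laminin gene Lamb3 (chromosome 1, 193207699 to 193343878) fell 2.35-fold, with the call kept in 4 of the 6 fits that left out 1 sample. The keratin gene Krt5 was at 209 and 237 in castrated samples 1 and 3 and at 1367 and 873 in castrated samples 2 and 4. In intact samples it was at 787 and 910. Over the list, castrated sample 4 lay a median of 1.11 above the mean of the other castrated samples on the log2 scale. Progenitor-like luminal genes had a median of -0.44 (camera adjusted p = 0.0381, and adjusted p = 0.667 with an estimated correlation), with 1 of 12 lower, the stem cell antigen gene Prom1 at 2.09-fold, of whose exon bases an antisense gene covers 5.91% and whose call was kept in 2 of the 6 fits that left out 1 sample. This call was lost with quantile normalization (adjusted p = 0.124), with array weights (adjusted p = 0.21) and without intact sample 2 or castrated sample 1, 3 or 4 (adjusted p = 0.134, 0.103, 0.0862 and 0.135). Endothelial genes (median -0.41) and fibroblast genes (median -0.43) were also called lower, with 0 of 14 and 0 of 22 past the limma threshold (5 and 5 at an unadjusted p under 0.05, 0 and 0 in edgeR, 2 and 3 in DESeq2) and adjusted p of 0.785 and 0.847 with an estimated correlation. The fibroblast call was lost without castrated sample 1 (adjusted p = 0.103). Smooth muscle genes (median 0.76) and adipocyte genes (median 1.30) were called higher, with adjusted p of 0.585 and 0.585 with an estimated correlation and 0.169 and 0.239 in fry. Past the limma threshold were 0 of 12 and 0 of 7 over all genes, and 7 and 2 adjusted over the list alone. At an unadjusted p under 0.05 there were 7 and 3, edgeR called 0 and 0, and DESeq2 7 and 3.

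Amino acid response genes had a median of -0.29 (camera adjusted p = 0.000302, and adjusted p = 0.17 with an estimated correlation), with 2 of 20 lower and 4 adjusted over the list alone. Mthfd2, a mitochondrial folate enzyme (chromosome 6, 83305691 to 83325908), fell 3.31-fold and Phgdh, the first enzyme of serine synthesis, 2.43-fold. With all samples, Phgdh lost its limma call with no filter (adjusted p = 0.0718) and without a mean-variance trend (adjusted p = 0.0610). Fatty acid and cholesterol synthesis genes had a median of -0.53 (camera adjusted p = 1.21e-07, and adjusted p = 0.416 with an estimated correlation), with 0 of 28 past the limma threshold over all genes and 10 lower adjusted over the list alone (14 at an unadjusted p under 0.05, 0 in edgeR, 9 in DESeq2). Steroid receptor and metabolism genes had a median of 0.50 (camera adjusted p = 0.000302, and adjusted p = 0.17 with an estimated correlation), with 0 of 14 past the threshold and 5 higher adjusted over the list alone (6 at an unadjusted p under 0.05, 0 in edgeR, 5 in DESeq2). With 1 sample left out, Mthfd2 kept its call in 4 of 6 fits and Phgdh in 1.

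Proliferation genes (median -0.25), antigen presentation genes (median -0.51), interferon response genes (median -0.33) and endoplasmic reticulum folding genes (median -0.13) were called lower by camera. Their adjusted p was 0.811, 0.667, 0.811 and 0.847 with an estimated correlation. Cytosolic ribosomal protein genes were called higher with a median of 0.18, positive in 75 of 78 (adjusted p = 0.847 with an estimated correlation). In these 5 lists limma called 0 genes, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 5, 6, 2, 3 and 1 genes, in that order, edgeR called 0 in each, and DESeq2 called 1, 2, 1, 2 and 0. The endoplasmic reticulum call was lost without intact sample 2 or castrated sample 4 (adjusted p = 0.0747 and 0.223). With all samples, camera made no call for the other lists: ribosome biogenesis (median -0.02), the PI3K-AKT-mTOR pathway (0.00), polyamine metabolism (-0.03), oxidative phosphorylation (0.01), glycolysis (-0.10), luminal epithelium (-0.23, called lower on the values as deposited at an adjusted p of 0.0477), neuroendocrine cells (-0.83), immediate early genes (-0.05) and Schwann cells (0.00). Oxidative phosphorylation genes were called higher without castrated sample 4 (median 0.13, adjusted p = 0.00111) and with array weights (adjusted p = 0.0344). Neuroendocrine genes were called lower without intact sample 1 (median -1.26, adjusted p = 0.00126) and with no filter (adjusted p = 0.0369). Luminal genes were called lower without castrated sample 1 or 3 (adjusted p = 0.0163 and 0.0401), and glycolysis genes without castrated sample 3 (adjusted p = 0.0140). Ribosome biogenesis genes were called higher without intact sample 1 (adjusted p = 0.0470) and lower without intact sample 2 (adjusted p = 0.00899). Schwann cell genes were called lower without intact sample 1 (adjusted p = 0.0133) and higher without intact sample 2 (adjusted p = 0.0207).

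**Figure D4:**
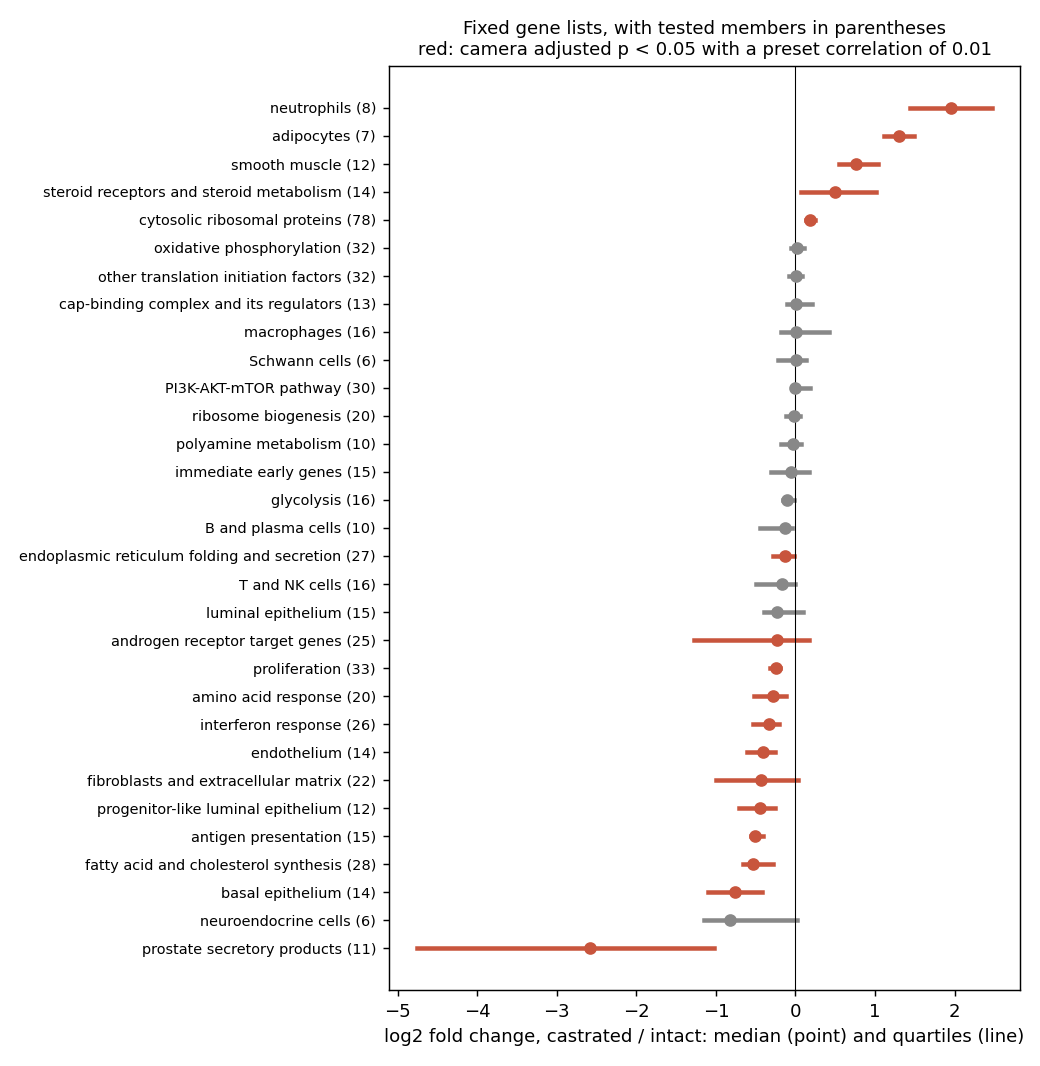
Median log2 fold change, castrated over intact, with quartiles as lines, for the 31 gene lists tested, the number of tested members in parentheses, and camera calls at the preset correlation in red. Medians run from -2.58 for secretory genes to 1.95 for neutrophil genes, and none of the calls held with an estimated correlation.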

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

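The tests of castrated sample 4 were chosen after its values were seen, and that of leukocytes and stroma replaced one on fewer of these lists, whose genes lay higher in it. Among the castrated samples, 3 of 37 named genes had 1 sample whose gap to the nearest of the others was large relative to the range of all 4 on the log2 scale, where chance gives about 1 in 20. The other 2 of 39 had at most 3 reads in each castrated sample and were left out. Peg10 was at 14.9 rescaled CPM in castrated sample 4, against 34.9 to 40.0 in the others. Mroh4 was at 0.287 in castrated sample 2, against 0 to 0.0352, and Eif4e was at 110.4 in castrated sample 1, against 97.0 to 97.7.

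Castrated sample 4 stood apart from castrated samples 1 and 3, with which it correlated at 0.941 and 0.954. Castrated sample 2 correlated at 0.970 with castrated sample 4 and at 0.969 and 0.974 with castrated samples 1 and 3. Leaving out castrated sample 4 raised the count of called genes from 274 to 1052. The reads of castrated sample 4, 59170793 and the most of any sample, argue against shallow sequencing of it. A first test of an intact sample under a castrated label fell short of its bound of 7 in 8: of 13 androgen receptor targets called without it, 9 lay nearer the other castrated samples, and 4 (Homer2, Elovl7, Maf and Ppap2a) nearer the intact ones. A further test, added because of that outcome, argues against the mislabel, since it lay below both intact samples in 83.3% of the 586 genes called lower without it, with Fkbp5 at 34.2 and Zbtb16 at 0.565. A larger share of leukocytes and stroma of every kind is argued against. In castrated sample 4, adipocyte genes lay below the mean of the other castrated samples, with an upper quartile of -0.87. So did B cell genes (median -0.57), and smooth muscle genes had a median of -0.09. Fibroblast, endothelial, macrophage, T and NK cell and Schwann cell genes had lower quartiles of 0.53, 0.41, 0.45, 0.19 and 0.08. Neutrophil genes had a median of 0.34. A larger share of several of these types is thus not argued against. Basal genes lay highest of the lists (1.11), and differences in single cell types or in time since castration, not given in the labels, stay open.

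The 6 samples can be split into 2 and 4 in 15 ways, too few for a share under 0.05. The real split gave 274 genes, as many as in 1 of the 15 splits, and the highest of the others gave 16.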

How the results depend on the processing

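The count of 274 genes stayed within 1.5 times under other pseudocounts, the stricter filter, other scalings, other moderation settings and edgeR (203 to 269). It was 170 with no filter (more genes tested), 954 with array weights, which gave castrated sample 4 the lowest weight, and 1293 with DESeq2, whose simulated calls were 27.3% false. The causes of these shifts in the count were not tested. Leaving out 1 sample gave 1 to 1052 genes, and with 1 intact sample left, that sample is assumed to vary like the castrated ones. Of the 31 lists, 17 were called, 16 to 20 with 1 sample left out, 5 by fry and 0 by camera with an estimated correlation (4 at an unadjusted p under 0.05). The replicate block gave 417 genes, 169 of them shared with the 274, and 16 lists, without the progenitor-like luminal and endoplasmic reticulum lists and with oxidative phosphorylation. The groups share only numbers 1 and 2, so the block fit compared castrated with intact samples within those numbers alone. The castrated samples with other numbers, castrated sample 4 among them, added nothing to its fold changes. The 417 genes are thus not a result of the full set. Deviations of the samples that share a number correlated at 0.0754 and 0.226, so nothing shows that the numbers pair the samples.

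For single named genes, 591 results under the alternatives kept their side of the threshold, 134 lost the call and 0 reversed with a call in either fit. A change of sign with no call in either fit was counted as kept. Such changes occurred for Eif4e (log2 changes from -0.085 to 0.179), Eif4a1 (-0.106 to 0.113) and Eif4g1 (-0.0375 to 0.0873). Fkbp5 was called under 19 of 19 alternatives. Of list medians, 587 were counted as kept by the same rule, 40 lost a call, 13 gained one, 2 reversed and 6 moved with no test. Medians from edgeR and DESeq2 had no list test. They were counted as kept if they moved by less than the SD of the list's mean between castrated samples. With 1 sample left out the median of ribosome biogenesis genes ran from -0.140 (without intact sample 2) to 0.0680 (without intact sample 1) and that of Schwann cell genes from -0.42 (without intact sample 1) to 0.378 (without intact sample 2), each called by camera at these ends and not with the full set. The values as deposited shifted the median gene by 0.05 on the log2 scale. Depth did not limit named genes other than those with few reads in a group.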

Other observations

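Tests of the Foxi1-related and neutrophil genes were chosen after those patterns were seen, and so were the genes named here; the test of a smaller share of the main cell type replaced one on fewer lists. The bound of the test on blood was written before its values were seen. The epithelial sodium channel subunits Scnn1b and Scnn1g rose with log2 changes of 2.66 and 2.51 (limma adjusted p = 0.0269 and 0.0429), higher in 4 of 4 castrated samples than in both intact ones, while Scnn1a was at 149 ± 66.5 and 137 ± 25.5. Scnn1g was at 2.74 and 7.91 rescaled CPM in intact samples 1 and 2, so the size of its rise depends on single samples. Umod, a glycoprotein gene known from the kidney, rose with a log2 change of 2.22, from 0.275 ± 0.0421 to 3.16 ± 0.677. Among lower genes were Lbp, which binds bacterial lipopolysaccharide (251 ± 44.2 to 43.7 ± 15.6), the surface antigen gene Ly6c1 (950 ± 86.3 to 156 ± 50.2) and the retinal dehydrogenase gene Aldh1a1 (153 ± 108 to 13.1 ± 4.65). Arg2, the 1 called gene of polyamine metabolism, fell from 34.4 ± 1.57 to 14.3 ± 2.84.

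Foxi1 and the proton pump subunits Atp6v0d2 and Atp6v1g3 rose and prompted a list of genes of Foxi1-expressing acid-secreting cells, whose other 15 tested members had a median log2 fold change of 0.83, 0 of them called by limma (7 at an unadjusted p under 0.05, 0 in edgeR, 4 in DESeq2), with Slc26a4, the most abundant, at 62.7 ± 13.2 and 58.1 ± 40.4. Kidney carry-over is argued against by 11 abundant kidney genes, the highest of which, Umod, added to that list after its rise was seen, averaged 3.16 rescaled CPM in castrated samples against 25.5 for Foxi1. Epididymis was tested likewise, and the highest of 8 genes, Crisp1, averaged 2.02. Crisp1 was at 2.32 to 3.07 in castrated samples 1 to 3, 0.194 in castrated sample 4 and at most 0.0936 in intact samples. That test cannot decide, since nothing here shows that such genes stay expressed after castration. A smaller share of the main cell type with no other change would raise all other types alike, but their lists moved apart. Basal genes had an upper quartile of -0.42, while smooth muscle, adipocyte and neutrophil genes had lower quartiles of 0.54, 1.11 and 1.44. The test cannot exclude a smaller share together with changes in other types, which also moves lists apart. More Foxi1-expressing cells, or more expression of Foxi1, Atp6v0d2 and Atp6v1g3 per cell after castration, may also account for their rise, which bulk RNA leaves open.

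Neutrophil genes rose without the genes of other leukocytes, whose upper quartile was 0.11 against a lower quartile of 1.44, which argues against more leukocytes of every kind. Residual blood is argued against by 4 red cell and platelet genes with an upper quartile of 1.19, a thin test, since Ppbp had a log2 difference of 3.60 with an SE of 2.05 and the haemoglobin genes were at or near 0 in every sample. The neutrophil attractant genes Cxcl5 and Cxcl15 rose with log2 changes of 2.30 and 1.73 (limma adjusted p = 0.0311 and 0.0496), higher in 4 of 4 castrated samples, while Cxcl1 was at 24.1 ± 21.0 and 23.6 ± 7.66. Intact samples 1 and 2 differed, at 254 and 104 rescaled CPM for Cxcl5 and 101.5 and 204.6 for Cxcl15, so the size of these rises depends on single samples. Recruitment of neutrophils through these chemokines may be involved, a hypothesis that no test here addresses.

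The skeletal muscle genes Acta1 and Ckm were at 5.63 and 3.02 rescaled CPM in castrated sample 1, against at most 1.33 and 0.0539 in the other samples.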
